A study of Mus musculus with 12 samples.

How the data were processed

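The series measured polyadenylated RNA in induced MEL cells with 12 libraries in 4 groups of 3. Per the labels, RNA was isolated with an RNeasy kit and libraries were made with the TruSeq RNA kit V2, which does not mark the strand. Per the submitters' processing notes, the tools were cutadapt 1.1, TopHat 1.4.1, HTSeq 0.5.3p9 and DESeq 1.10.1, with genome build mm9. The order of these tools, their settings and the gene annotation are not given in the sources used here. The deposited values are whole-number counts per Ensembl gene, 37991 genes in each file, not normalized. Each file closes with 5 rows that name no gene: reads outside genes, ambiguous reads, reads of low quality, unaligned reads and reads that aligned to several places. These rows were left out of library sizes and tests. Reads that aligned to several places made up 38.69 to 53.31% of the tallied reads, reads outside genes 2.117 to 6.133% and ambiguous reads 1.33 to 1.809%. The share aligned to several places was 50.6 to 53.31% in control and 42.69 to 48.51% in KD. It was 42.26 to 47.12% in FL and 38.69 to 39.22% in delta45, so each comparison with control also differed in this share. Reads of nearly identical genes are therefore partly lost, and the values of Hba-a1 and Hba-a2, and of Hbb-bs and Hbb-bt, are uncertain as to which copy they came from. Without strand information, a gene and an antisense or overlapping partner cannot be told apart.

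Gene symbols came from a supplied table that matched 32919 of the 37991 identifiers. Unmatched identifiers held 0.5384 to 0.8236% of gene reads. Gene order along chromosomes came from the RefSeq annotation of GRCm38, a build other than the authors', and no coordinate from it is given. Gene reads ranged from 8783970 to 20464959 per library. Pearson correlations of log2 CPM between replicates were 0.9844 to 0.9905 in control, 0.9551 to 0.9773 in KD, 0.9931 to 0.9942 in delta45 and 0.9888 to 0.994 in FL. No 2 libraries of a group agreed within counting noise, the smallest chi-square per degree of freedom being 2.216.

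Genes were kept by filterByExpr, which left 12837. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with a mean for each of the 4 groups and all 12 libraries in the fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 6 comparisons. Standard errors are the absolute log2 change divided by the root of the F statistic. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so the calls rest on the spread shared across genes. CPM values are computed here from the deposited counts. A gene without reads in a group was given a bound on its fold, computed against 3 reads over the group. A gene with 1 to 3 reads was given a ratio with an exact binomial interval at the 95% level. Bounds and intervals cover counting error only, as the libraries have no molecular identifiers.

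Before the data were examined, 21 gene lists were fixed: globins, heme synthesis, erythroid membrane and cytoskeleton, other erythroid maturation genes, iron handling, LDB1 complex and partners, FOG1 and NuRD, stem and progenitor genes, megakaryocyte, myeloid, mast and basophil, lymphoid, and stromal and endothelial markers, DNA replication and mitosis, cell cycle inhibitors, ribosome biogenesis and MYC targets, autophagy, p53 targets and apoptosis, interferon response, hypoxia and glycolysis, and unfolded protein and amino acid stress. They held 425 entries, of which 420 were matched. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusting over the lists within a comparison. The genes named were also fixed by rule. The rule took Ldb1 and all globins. It took up to 10 genes each way by fold for KD against control and FL against delta45, and up to 5 for the others. Those had to pass the test, reach 5 CPM and have no overlap between libraries, with clone, predicted-gene, pseudogene and histone names left out. It also took up to 4 members of each other list by adjusted p, and a gene named in 1 comparison could be given in others. A gene withheld for evaluation is not reported here.

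The tests were checked on simulated counts for KD against control in 12538 genes with 50 genes changed at each fold. The edgeR test recovered 20% at 1.5-fold, 64% at 2-fold, 88% at 4-fold and 96% at 8-fold, with 9 false calls. Of the tested genes, 49.7 to 64.4% were called in the real comparisons, far more than were changed here. These rates therefore do not measure recovery in the real comparisons. The heme synthesis list raised 2-fold in KD was called, and 0 other lists were. Genes were simulated independently of each other, so false list calls among correlated genes were not checked. In the data the estimated correlation was 0.514 for globins. The alternatives tried were RLE scaling, library totals only, the globin list left out, other count filters, a replicate block, DESeq2 1.42.0, limma voom, a test against a fold change of 1.5, fits on the compared groups alone and each library left out. Thinning every library to equal depth was added after seeing the data.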

Results

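Polyadenylated RNA was sequenced from 12 libraries of induced MEL cells, a mouse erythroleukemia line that can be driven toward red cell maturation in culture. The libraries fell into 4 groups of 3. The control group was the unmodified line. The knockdown group (KD) had reduced LDB1, a LIM-domain-binding protein that joins the erythroid transcription factors GATA1, TAL1 and LMO2 in a complex. The other 2 groups were knockdown cells that expressed either full-length LDB1 (FL) or an LDB1 construct named delta 4/5 (delta45). Reads assigned to genes ranged from 8783970 to 20464959 per library. Levels are CPM (counts scaled to library size) after TMM normalisation, given as mean ± SD with n = 3 libraries per group. Changes are log2 ± SE from edgeR's quasi-likelihood fit to all 12 libraries, with Benjamini-Hochberg adjusted p-values. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

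The targeted gene followed the group labels in each library. Ldb1 (ENSMUSG00000025223) stood at 718 ± 71.2 CPM in control and 130 ± 31.1 CPM in KD, 5.54-fold lower (log2 change -2.47 ± 0.16, edgeR adjusted p = 1.55e-07). The 3 KD libraries held 159.2, 132.2 and 97.1 CPM. In delta45 Ldb1 was at 765 ± 15.4 CPM, which was not called different from control (log2 change 0.09 ± 0.151, edgeR adjusted p = 0.607). In FL it reached 3439 ± 244 CPM, 4.79-fold above control and 4.49-fold above delta45 (edgeR adjusted p = 1.25e-07). The constructs were therefore compared at unequal amounts of Ldb1 mRNA, and the counts do not tell a construct's reads from those of the cells' own gene.

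**Figure D1:**
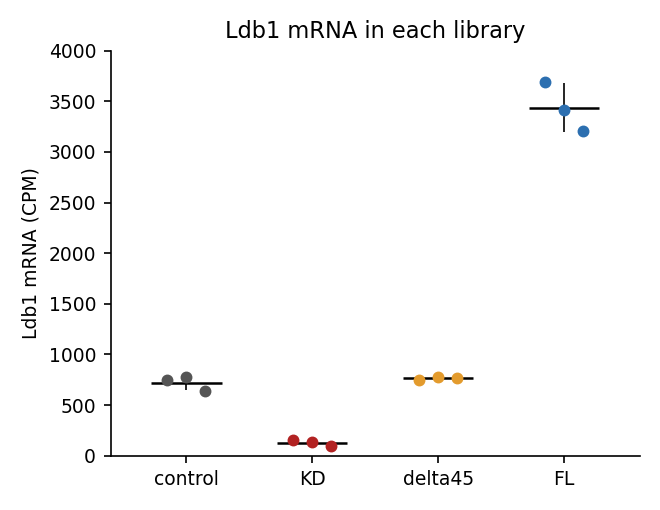
Ldb1 mRNA in CPM (vertical axis) for each of the 12 libraries, by group. Points are libraries, horizontal lines the group means and vertical lines 1 SD; the delta45 libraries lie between 750.4 and 781.2 CPM, beside control, and the FL libraries between 3210 and 3696 CPM.

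Knockdown against control asked what the loss of LDB1 changed in induced cells. Globin mRNA fell: all 7 globin genes tested were lower in KD. Among them Hba-a2, Hba-x and Hbq1a were scarce, at 5.06, 2.89 and 0.817 CPM in control. They had 17, 7 and 5 reads over the KD libraries, so their changes rest on few reads. Hba-a1, an adult alpha-globin gene, was at 843 ± 310 CPM in KD and 4780 ± 194 CPM in control, 5.67-fold lower (log2 change -2.50 ± 0.233, edgeR adjusted p = 3.12e-06). The adult beta-globin genes Hbb-bs and Hbb-bt were 8.03-fold and 3.25-fold lower, although reads of such near-identical copies can be lost or assigned to the wrong copy. Hbb-bs varied in KD, at 269 ± 173 CPM, and its log2 change of -3.01 was -3.62 without KD replicate 3. Alas2, the erythroid enzyme that starts heme synthesis, was 3.34-fold lower at 488 ± 151 CPM. Car1, a carbonic anhydrase abundant in red cells, was 182-fold lower, from 495 ± 78.0 to 2.72 ± 0.601 CPM (edgeR adjusted p = 1.12e-10).

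Of 20 tested genes for the red cell membrane and its skeleton, 14 fell and 1 rose (1 higher and 14 lower adjusted over the list alone). Among them Add2 (beta-adducin) was 5.2-fold and Ermap 4.01-fold lower. The globin list (0 higher and 7 lower adjusted over the list alone) had a median log2 change of -2.50 and the membrane list -0.98 (camera adjusted p = 0.000319 and 0.000633). With an estimated correlation the adjusted p-values were 0.348 and 0.77. Ribosome biogenesis and MYC target genes went the other way, with 18 of 25 higher and 0 lower (18 higher and 1 lower adjusted over the list alone). Polr1b, a subunit of RNA polymerase I, was 2.69-fold and the nucleolar gene Bop1 2.36-fold higher (camera adjusted p = 2.28e-05 for the list, and adjusted p = 0.107 with an estimated correlation). Of 14 FOG1 and NuRD genes 9 rose and 1 fell (10 higher and 1 lower adjusted over the list alone), led by the remodeller Chd3 at 2.48-fold higher, while Mbd2 was 1.88-fold lower (camera adjusted p = 0.0188, and adjusted p = 0.155 with an estimated correlation).

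Lists without a camera call still held changed genes. Heme synthesis had 6 of 13 genes lower and 2 higher (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.378), with Ppox 3.97-fold lower and Uros 3.71-fold higher. Without control replicate 3, 3 heme genes were lower, and without KD replicate 1, 4 were higher. Megakaryocyte markers went both ways, with 5 of 15 higher and 6 lower (6 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.931). The platelet chemokine gene Pf4 was 6.71-fold higher, whereas the platelet integrin gene Itga2b was 2.91-fold and the platelet tubulin gene Tubb1 18.5-fold lower. Of 15 stem and progenitor genes 6 rose, among them Gata2, a transcription factor of early progenitors, at 4.56-fold, and 2 fell (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.415). The number of lower stem and progenitor genes was 6 without KD replicate 1 and 1 without KD replicate 3, without control replicate 3 or with library totals only. Of 24 other erythroid maturation genes 8 fell and 5 rose, (5 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.159, and 0.0266 without KD replicate 3). The number of higher genes in that list was 8 without KD replicate 1, 2 without KD replicate 3 and 3 without any 1 control library. Of 5 lymphoid markers 4 were higher and 0 lower in KD, Lck 2.69-fold higher (4 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0722, against 0.0478 without KD replicate 3 and 0.021 with no low-count filter for lymphoid markers). DNA replication and mitosis genes split, with 9 of 32 higher, such as Pcna at 2.3-fold, and 13 lower, such as Plk1 at 2.18-fold (9 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.74). Of 25 interferon response genes 18 were higher and 0 lower (19 higher and 0 lower adjusted over the list alone), but the KD libraries differed widely. Their mean log2 list levels relative to control were -1.65, 1.69 and 2.95 in replicates 1, 2 and 3, and Isg15 stood at 902 ± 1082 CPM in KD against 49.6 ± 7.99 in control. The number of higher interferon genes was 6 without KD replicate 3, 8 without control replicate 1 and 10 without control replicate 2 (camera adjusted p = 0.125 with all libraries for the interferon response list, 1.67e-09 without KD replicate 1 and 0.0221 with no low-count filter).

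Several of the largest changes among the named genes were in genes with no reads in 1 of the groups. Tmsb4x (thymosin beta-4) had 0 reads in the control libraries and 538 ± 178 CPM in KD, at least 6510-fold higher when control was set at 3 reads over the group. On the same basis Egln3, an oxygen-sensing prolyl hydroxylase, was at least 784-fold and the matrix protease Mmp14 at least 704-fold higher. These genes were also read with full-length LDB1 put back: Tmsb4x stood at 4291 ± 251 CPM, Egln3 at 159 ± 1.57 CPM and Mmp14 at 44.1 ± 4.76 CPM in FL. Of 13 genes with 0 reads in control and 5 CPM or more in KD, 10 were at 5 CPM or more in both FL and delta45. Of the 12 placed in gene order, Tmsb4x and Prps2 lay next to each other among tested genes. These 2 had a neighbour in the set, against a mean of 0.043 in random sets (permutation p = 0.0215). For such genes a difference between the cell lines, apart from LDB1, cannot be told apart from the knockdown. Hcls1, a cytoskeletal signalling gene of blood cells, was at 68.2 ± 3.42 CPM in control with 0 reads in KD, at least 796-fold lower. The cadherin gene Cdh19 was at least 746-fold, the surface receptor Cd48 at least 411-fold and the kinase gene Syk at least 392-fold lower. These 4 were among 21 genes at 5 CPM or more in control with 0 reads in KD, of which 17 had 0 reads in FL as well. In all, 6380 of 12837 tested genes differed, 3283 higher and 3097 lower in KD (edgeR, Benjamini-Hochberg adjusted p under 0.05). A test against a fold change of 1.5 called 2387 genes.

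FL against KD asked what full-length LDB1 changed when it was put back into knockdown cells. All 7 globin genes rose, although Hba-a2, Hba-x and Hbq1a stayed scarce at 6.78, 0.839 and 2.06 CPM in FL. Hba-a1 reached 9624 ± 1707 CPM, 11.4-fold above KD, and Hbb-bs 9582 ± 2136 CPM, 35.6-fold above KD (log2 change 5.15, and 5.77 without KD replicate 3, edgeR adjusted p = 3.94e-07). Alas2 was 10.6-fold higher at 5166 ± 394 CPM, and Tfrc, the transferrin receptor, 11-fold higher. Genes for DNA replication and mitosis fell together, 31 of 32 lower and 0 higher. The replication helicase genes Mcm5 and Mcm3 were 5.36-fold and 5.03-fold lower, and the progenitor transcription factor Myb was 25.6-fold lower at 2.60 ± 0.491 CPM (log2 change -4.72, and -4.11 without KD replicate 1).

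The globin list had a median log2 change of 3.51 (7 higher and 0 lower adjusted over the list alone, camera adjusted p = 7.3e-05, and adjusted p = 0.284 with an estimated correlation). Of 20 membrane genes 16 rose and 3 fell (16 higher and 3 lower adjusted over the list alone), with Rhag 7.27-fold and Tmod1 (tropomodulin) 4.64-fold higher (camera adjusted p = 7.3e-05, and adjusted p = 0.326 with an estimated correlation). Of 13 heme synthesis genes 7 rose and 0 fell (7 higher and 0 lower adjusted over the list alone), Fech (ferrochelatase) 3.4-fold, and 2 fell with library totals only (camera adjusted p = 0.00389, and adjusted p = 0.326 with an estimated correlation). Other erythroid maturation genes gave 12 of 24 higher and 5 lower (13 higher and 5 lower adjusted over the list alone); Car2 was 5.47-fold higher and the transferrin receptor gene Tfr2 5.28-fold lower (camera adjusted p = 0.0141, 0.0689 without KD replicate 1, and adjusted p = 0.537 with an estimated correlation). The DNA replication and mitosis call (0 higher and 31 lower adjusted over the list alone, median -1.76) held with both settings (camera adjusted p = 3.29e-15, and adjusted p = 0.00575 with an estimated correlation). Ribosome biogenesis genes were 19 of 25 lower (0 higher and 20 lower adjusted over the list alone), with Srm (spermidine synthase) 3.59-fold lower (camera adjusted p = 0.000259, and adjusted p = 0.136 with an estimated correlation).

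Interferon response genes were 23 of 25 lower in FL (0 higher and 24 lower adjusted over the list alone), with Bst2 45.3-fold lower against variable KD libraries at 891 ± 804 CPM (camera adjusted p = 0.000753, and adjusted p = 0.623 with an estimated correlation). The log2 change of Bst2 was -5.50, and -4.61 without KD replicate 3. The list's median was -4.70, or -4.48 with the member lacking reads set at its bound. KD replicate 1, at a mean log2 list level of -1.65 relative to control, lay near the FL libraries (-2.25 to -2.01). KD replicates 2 and 3 stood at 1.69 and 2.95. Of 21 autophagy and organelle clearance genes 10 rose and 1 fell (9 higher and 1 lower adjusted over the list alone), with the mitophagy receptor Bnip3l 2.68-fold and Foxo3 3.47-fold higher (camera adjusted p = 0.00698, and adjusted p = 0.344 with an estimated correlation). With library totals only, 6 autophagy genes were higher and 3 lower, and the median went from 0.31 to 0.05. Of 5 lymphoid markers 3 fell, Cd3g 35.6-fold and Lck 3.34-fold (0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0397, 0.0772 with library totals only, and adjusted p = 0.284 with an estimated correlation). In all, 7445 genes differed, 3382 higher and 4063 lower in FL (edgeR, Benjamini-Hochberg adjusted p under 0.05), or 45.4% higher. Scaling by library totals only gave 26.7% higher, with the median of all genes shifted by -0.27 log2, and the test against a fold change of 1.5 called 3510.

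The delta45 construct against KD asked the same question of the altered construct. Globin genes did not move together: 2 of 7 were higher and 1 lower. The number higher was 1 without KD replicate 1, KD replicate 2 or delta45 replicate 3, and 3 without KD replicate 3. Hba-a1 stood at 769 ± 125 CPM and was not called different from KD (log2 change -0.13 ± 0.221, edgeR adjusted p = 0.62). Hbb-bt was 3.68-fold lower than in KD, and Hbb-bs 2.38-fold higher (log2 change 1.25, and 1.87 without KD replicate 3). Reads of these near-identical copies are uncertain as to their source, so their opposite directions are uncertain too. The globin list as a whole held a mean of 0.1537% of gene reads in KD and 0.162% in delta45. Of 24 other erythroid maturation genes 8 rose and 6 fell (8 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.807), Car2 being 2.5-fold higher and Tfr2 3.08-fold lower. Without KD replicate 1, 11 of them were lower. Alas2 was 1.6-fold lower, in a heme synthesis list with 5 of 13 higher and 2 lower (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.347). The number of higher heme genes was 3 without KD replicate 1 or delta45 replicate 3, and that of lower ones 1 without KD replicate 2. Genes of glycolysis and the hypoxia response fell, 21 of 22, with Ndrg1 19.1-fold and the glucose transporter Slc2a3 5.57-fold lower.

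The globin list was not called (2 higher and 1 lower adjusted over the list alone, median 0.35, camera adjusted p = 0.875). Of 20 membrane genes 12 rose and 4 fell (12 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.065, against 0.0228 without KD replicate 2, 0.0182 without KD replicate 3 and 0.0377 with no low-count filter for the erythroid membrane and cytoskeleton list). The membrane anchor gene Ank1 was 3.56-fold higher, while Slc4a1, the anion exchanger of the red cell membrane, stood at 1.99 ± 0.176 CPM in delta45 and 7.56 ± 5.97 in KD, and Add2 at 23.7 ± 2.28 and 44.0 ± 20.03 CPM. Ribosome biogenesis genes rose, 21 of 25 higher and 1 lower (24 higher and 1 lower adjusted over the list alone), with Polr1b 3.68-fold higher (camera adjusted p = 6.39e-07, and adjusted p = 0.0591 with an estimated correlation). DNA replication and mitosis genes were 21 of 32 higher (22 higher and 0 lower adjusted over the list alone), with Cdc6 2.39-fold higher (camera adjusted p = 9.37e-05, and adjusted p = 0.0889 with an estimated correlation). Myc was 2.37-fold higher at 458 ± 34.2 CPM. The hypoxia and glycolysis list (0 higher and 21 lower adjusted over the list alone) had a median of -2.69 (camera adjusted p = 6.5e-13, and adjusted p = 0.186 with an estimated correlation).

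Megakaryocyte markers were 10 of 15 lower and 1 higher in delta45 (1 higher and 10 lower adjusted over the list alone), with Pf4 19.3-fold and the integrin gene Itgb3 6.31-fold lower (camera adjusted p = 0.00506, and adjusted p = 0.0889 with an estimated correlation). Interferon response genes were 24 of 25 lower (0 higher and 24 lower adjusted over the list alone; camera adjusted p = 9.24e-05, and adjusted p = 0.729 with an estimated correlation), with a median of -5.41, or -4.84 with the member lacking reads at its bound. KD replicate 1 stood apart from the other KD libraries, with a mean log2 list level relative to control of -1.65 against 1.69 and 2.95 in KD replicates 2 and 3, while the delta45 libraries lay between -2.55 and -2.45. Of 5 lymphoid markers 4 fell (0 higher and 4 lower adjusted over the list alone), Lck 7.45-fold (camera adjusted p = 0.0114, and adjusted p = 0.0896 with an estimated correlation). In all, 7693 genes differed, 3747 higher and 3946 lower in delta45 (edgeR, Benjamini-Hochberg adjusted p under 0.05), and 3506 in the test against a fold change of 1.5.

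FL against delta45 tested the difference between the constructs directly. Both lines were measured against the same KD libraries, so it is also the test of whether their changes from KD differed. All 7 globin genes were higher in FL, although the scarce Hba-a2, Hba-x and Hbq1a had 34, 5 and 30 reads over the delta45 libraries. Hbb-bt was at 3958 ± 169 CPM in FL and 94.0 ± 15.3 CPM in delta45, 42.1-fold higher (log2 change 5.40 ± 0.198, edgeR adjusted p = 8.65e-10), and Hba-a1 was 12.5-fold higher. The near-identical copy Hbb-bs differed by a smaller fold, at 9580 CPM in FL and 641 CPM in delta45. Reads of these copies are uncertain as to their source, so the fold of Hbb-bt alone is uncertain too. Alas2 was 16.9-fold higher in FL. All 32 DNA replication and mitosis genes were lower in FL, Mcm6 by 7.75-fold, and Myb was at 2.60 ± 0.491 CPM in FL against 93.7 ± 4.56 in delta45. Car1 was 74.8-fold lower in FL at 0.284 ± 0.111 CPM.

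**Figure D2:**
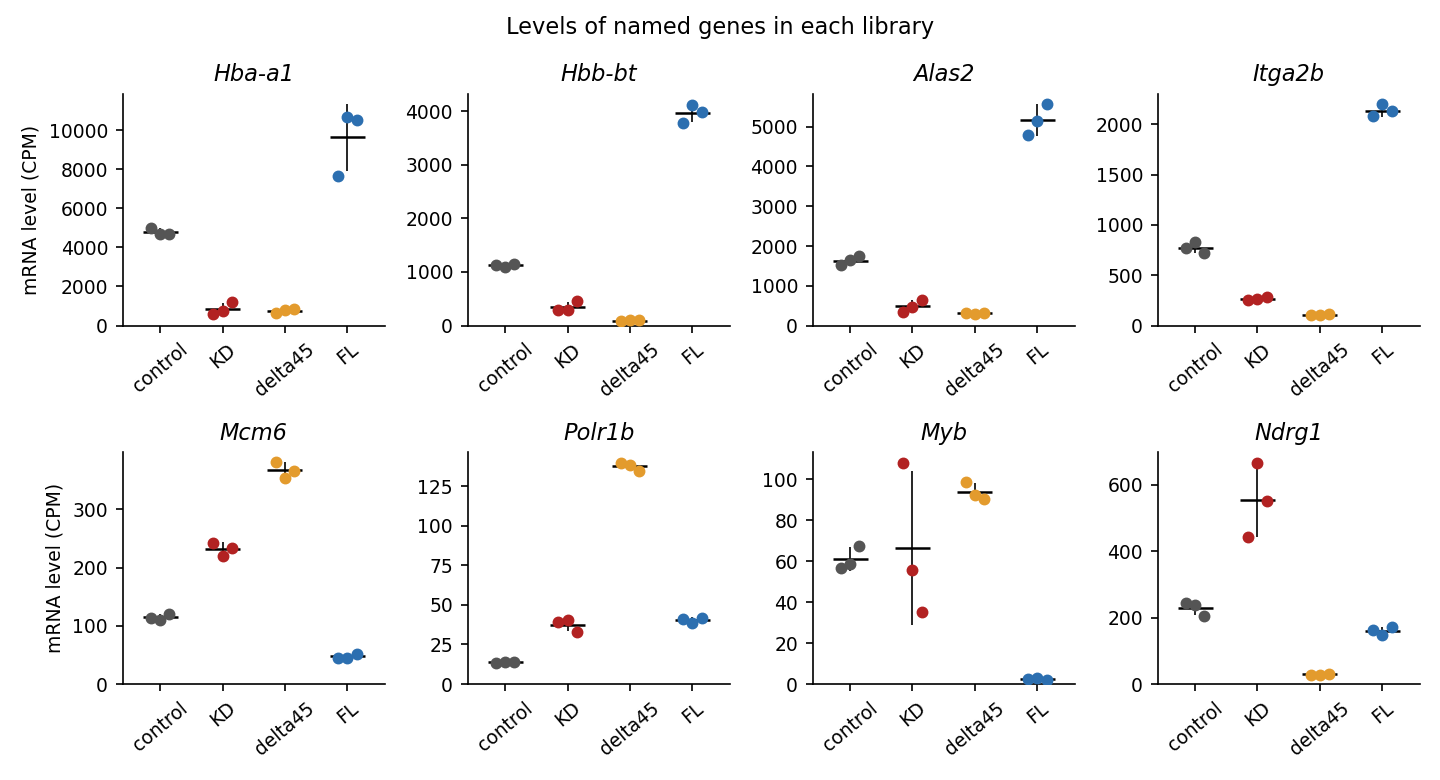
Levels of 8 genes in CPM (vertical axes, each from 0) for each of the 12 libraries, by group. Points are libraries, horizontal lines means and vertical lines 1 SD; Hbb-bt stands near 3958 CPM in FL and 94.0 CPM in delta45, while Mcm6 stands at 47.4 and 368 CPM.

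The globin list had a median log2 change of 3.28 (7 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000117, and adjusted p = 0.228 with an estimated correlation). Of 20 membrane genes 12 were higher and 4 lower in FL (14 higher and 4 lower adjusted over the list alone), Rhag 3.58-fold higher (camera adjusted p = 0.0055, and adjusted p = 0.471 with an estimated correlation). Other erythroid maturation genes gave 15 of 24 higher and 5 lower (15 higher and 5 lower adjusted over the list alone), with Fam210b 4.23-fold higher (camera adjusted p = 0.0105, and adjusted p = 0.471 with an estimated correlation). Heme synthesis genes gave 7 of 13 higher and 3 lower without a list call (8 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.056 for heme synthesis, against 0.0436 without FL replicate 1, 0.0192 with library totals only and 0.0125 with no low-count filter). Tal1 and Gata1, transcription factors of the LDB1 complex, were 2.39-fold and 1.96-fold higher in FL, in a list with 7 of 17 higher and 3 lower (7 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.219). The median of that list was 0.08, and -0.20 with library totals only, where 4 were higher and 4 lower.

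DNA replication and mitosis genes had a median of -2.40 (0 higher and 32 lower adjusted over the list alone, camera adjusted p = 6.32e-20, and adjusted p = 0.00223 with an estimated correlation). Ribosome biogenesis genes were 24 of 25 lower and 0 higher (0 higher and 24 lower adjusted over the list alone), Srm 6.24-fold and Dkc1 (dyskerin) 3.84-fold lower (camera adjusted p = 4.67e-12, and adjusted p = 0.00514 with an estimated correlation). Myc was 3.87-fold lower in FL. Hypoxia and glycolysis genes were 21 of 22 higher (21 higher and 0 lower adjusted over the list alone); Aldoc (an aldolase) was 11.4-fold and Egln3 1390-fold higher, from 0.115 ± 0.0344 to 159 ± 1.57 CPM (camera adjusted p = 1.28e-13, and adjusted p = 0.219 with an estimated correlation). Autophagy genes were 13 of 21 higher and 2 lower (15 higher and 2 lower adjusted over the list alone), Bnip3l 4.17-fold higher (camera adjusted p = 0.000657, and adjusted p = 0.32 with an estimated correlation).

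Megakaryocyte markers were 8 of 15 higher in FL and 0 lower (8 higher and 0 lower adjusted over the list alone), a call that held with both settings (camera adjusted p = 8.96e-05, and adjusted p = 0.0124 with an estimated correlation). Itga2b, the platelet integrin alpha-IIb gene, was at 2136 ± 60.2 CPM in FL and 110 ± 7.02 in delta45, and Pf4 was 21.8-fold higher. Beyond the lists, the receptor genes Il10ra and Adra2a were 152-fold and 48.8-fold higher in FL, while Nos1 was 50.5-fold and Angpt1 17.5-fold lower. In all, 6778 genes differed, 3310 higher and 3468 lower in FL (edgeR, Benjamini-Hochberg adjusted p under 0.05), or 48.8% higher. Scaling by library totals only gave 29.2% higher with a median shift of -0.28 log2, and the test against a fold change of 1.5 called 3233.

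**Figure D3:**
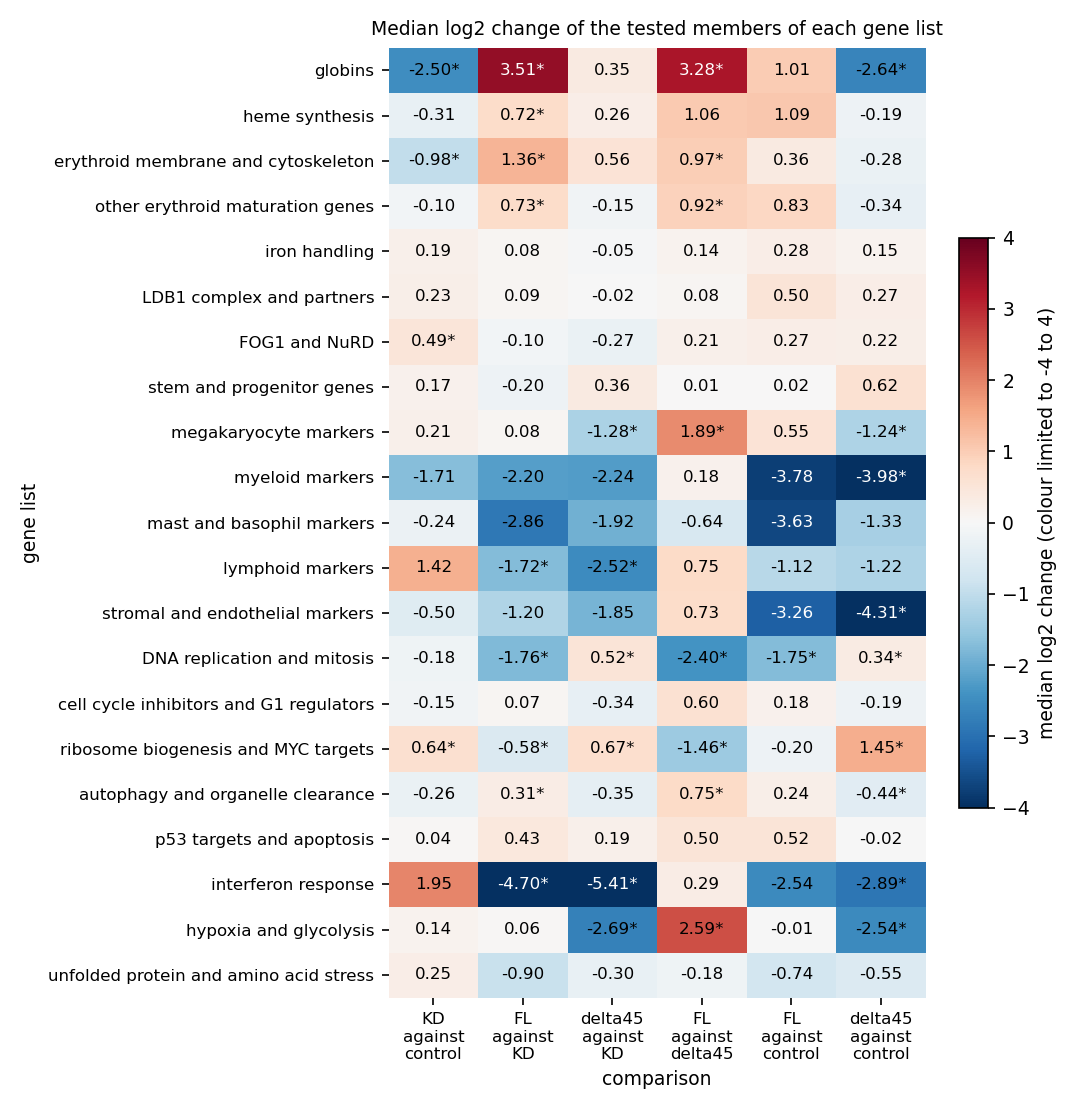
Median log2 change of the tested members of 21 gene lists (rows) in the 6 comparisons (columns), with the colour scale limited to changes of 4 either way and an asterisk where the camera adjusted p was under 0.05. The DNA replication and mitosis list stands at -1.76 in FL against KD and 0.52 in delta45 against KD.

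FL against control asked what differed from control with full-length LDB1 put back, whether or not the knockdown had changed it. Globin genes went both ways, 4 of 7 higher and 1 lower, Hba-a1 2.01-fold and Hbb-bs 4.43-fold higher and the embryonic Hba-x 3.45-fold lower (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.151). Fech was 2.74-fold and Tal1 3.43-fold higher. Car1 was at 0.284 ± 0.111 CPM in FL and 495 ± 78.0 in control, 1740-fold lower (edgeR adjusted p = 2.69e-11). DNA replication and mitosis genes were 31 of 32 lower and 1 higher (1 higher and 31 lower adjusted over the list alone), Cdt1, a replication licensing factor, 12.6-fold (camera adjusted p = 5.59e-13, and adjusted p = 0.00982 with an estimated correlation). It was the 1 list that camera called at the preset correlation with the main settings, whereas 8 were called with no low-count filter and 3 at equal depth or without control replicate 3. In KD against control the DNA replication and mitosis list was not called (median -0.18, camera adjusted p = 0.74). Slc25a45 and Mbd1 had 0 reads in FL, at least 488-fold and 424-fold lower. In all, 7616 genes differed, 3611 higher and 4005 lower in FL (edgeR, Benjamini-Hochberg adjusted p under 0.05), or 47.4% higher. Library totals only gave 31.8% higher with a median shift of -0.22 log2, and the test against a fold change of 1.5 called 3835.

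The delta45 construct against control asked the same of the altered construct. Although Ldb1 mRNA was not called different from control, 6 of 7 globin genes were lower and 0 higher. Hbb-bt was 12-fold, Hba-a1 6.22-fold and Alas2 5.34-fold lower. Hbb-bs, near-identical to Hbb-bt, fell by a smaller fold, from 2160 CPM in control to 641 CPM in delta45. Slc4a1 was 28.9-fold lower at 1.99 ± 0.176 CPM (edgeR adjusted p = 3.99e-06), in a membrane list with 9 of 20 lower and 2 higher (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.225). Ribosome biogenesis genes were higher, 24 of 25, with Polr1b 9.9-fold, Mybbp1a 5.58-fold and Myc 4.1-fold above control. Hypoxia and glycolysis genes were lower, 19 of 22, with Gpi1 7.65-fold lower. In KD against control that list was not called (median 0.14, camera adjusted p = 0.378).

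The globin list (0 higher and 6 lower adjusted over the list alone) had a median of -2.64 (camera adjusted p = 0.0085, and adjusted p = 0.514 with an estimated correlation). The ribosome biogenesis call (24 higher and 1 lower adjusted over the list alone) held with both settings (camera adjusted p = 2.42e-09, and adjusted p = 0.0207 with an estimated correlation). The hypoxia and glycolysis list (1 higher and 19 lower adjusted over the list alone) had camera adjusted p = 7.23e-08, and adjusted p = 0.514 with an estimated correlation. Megakaryocyte markers were 9 of 15 lower and 3 higher (3 higher and 9 lower adjusted over the list alone), Itga2b 7.06-fold lower (camera adjusted p = 0.0299, and adjusted p = 0.241 with an estimated correlation). Autophagy genes were 11 of 21 lower and 1 higher (1 higher and 11 lower adjusted over the list alone), Bnip3 25.7-fold lower (camera adjusted p = 0.0299, and adjusted p = 0.542 with an estimated correlation). All 6 stromal and endothelial markers tested were lower (0 higher and 6 lower adjusted over the list alone), Vim (vimentin) 4.2-fold (camera adjusted p = 0.00264, and adjusted p = 0.504 with an estimated correlation).

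Another 3 lists had calls in delta45 against control that lay near the threshold and ended under several settings. Of 8 myeloid markers 6 were lower and 1 higher (1 higher and 6 lower adjusted over the list alone), with Prtn3 (proteinase 3) 14.5-fold lower (camera adjusted p = 0.0477, and adjusted p = 0.531 with an estimated correlation). For the list of myeloid markers the camera adjusted p was 0.0561 without control replicate 2, 0.0519 without control replicate 3, 0.052 with RLE scaling and 0.0512 with the globin list left out. Genes of DNA replication and mitosis were 16 of 32 higher and 7 lower (16 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0477, and adjusted p = 0.514 with an estimated correlation), with 0.0644 without control replicate 2, 0.0555 without control replicate 3, 0.052 with RLE scaling, 0.0512 with the globin list left out and 0.0569 at equal depth. Genes of the interferon response were 16 of 25 lower (0 higher and 17 lower adjusted over the list alone; camera adjusted p = 0.0332, and adjusted p = 0.697 with an estimated correlation), with 0.0533 and 0.0555 without control replicates 2 and 3. In all, 8271 genes differed, 4096 higher and 4175 lower in delta45 (edgeR, Benjamini-Hochberg adjusted p under 0.05), and 4596 in the test against a fold change of 1.5.

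The last comparison followed the knockdown-changed genes into the construct lines. Of the 3097 genes lower in KD, 1326 (42.8%) were higher in FL than in KD and 603 (19.5%) lower. For delta45 the counts were 1144 (36.9%) higher and 761 (24.6%) lower. Between the constructs, 1072 (34.6%) were higher in FL than in delta45 and 613 (19.8%) lower. Globin and Alas2 mRNA were among the genes higher in FL than in KD and in delta45. Of the 3283 genes higher in KD, 1696 (51.7%) were lower in FL than in KD, 1376 (41.9%) lower in delta45 than in KD, and 1203 (36.6%) lower in FL than in delta45. In the opposite direction stood 368 (11.2%), 661 (20.1%) and 736 (22.4%). Against KD, 762 of the 3097 genes lower in KD were called higher in both construct lines and 1389 in neither. Another 564 were called higher in FL only and 382 in delta45 only. Of the 564, 474 were also higher in FL than in delta45, a test that shares the libraries that chose them. Against control, 1783 (57.6%) of the 3097 were still lower in FL and 2030 (65.5%) in delta45. Of the genes higher in KD, 923 were lower in both lines, 773 in FL only, 453 in delta45 only and 1134 in neither.

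In 20 simulated data sets with the construct libraries drawn at the KD means, each of the recovery counts averaged at most 0.1 genes and reached at most 1. The simulated lines did not differ from KD, so these counts measure false calls only. They do not tell recovery from other differences between the lines. Of the simulated genes lower in KD, a mean of 86.9% were still lower in FL than in control and 87.6% in delta45. Independent lists of the observed sizes would share 816 genes for FL and 904 for delta45 among the genes lower in KD, and 1039 and 1009 among those higher. For FL against delta45, a comparison that uses none of the libraries that chose the genes, independent lists would share 799 and 887. The 3 KD libraries are shared and too few to split with 2 in each part, so part of the excess in the counts against KD may come from them. Across 12067 genes the changes of FL and delta45 against KD correlated with r = 0.56 and rho = 0.49, against r = 0.51 with no effects simulated. Their covariance was 0.736 against 0.0334 simulated, a difference of 0.702. The covariance of the KD change with the FL change was -0.319 against -0.0327 simulated, and with the delta45 change -0.24 against -0.0358, differences of -0.287 and -0.204. Genes are not independent replicates, and no p-value is given. Scaling by library totals only moved 3 of these counts by over 1.5 times: 863 for genes lower in KD and higher in FL, 650 for those higher in FL than in delta45, and 1824 for genes higher in KD and lower in FL than in delta45. Without KD replicate 1, 1749 genes lower in KD were higher in delta45.

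**Figure D4:**
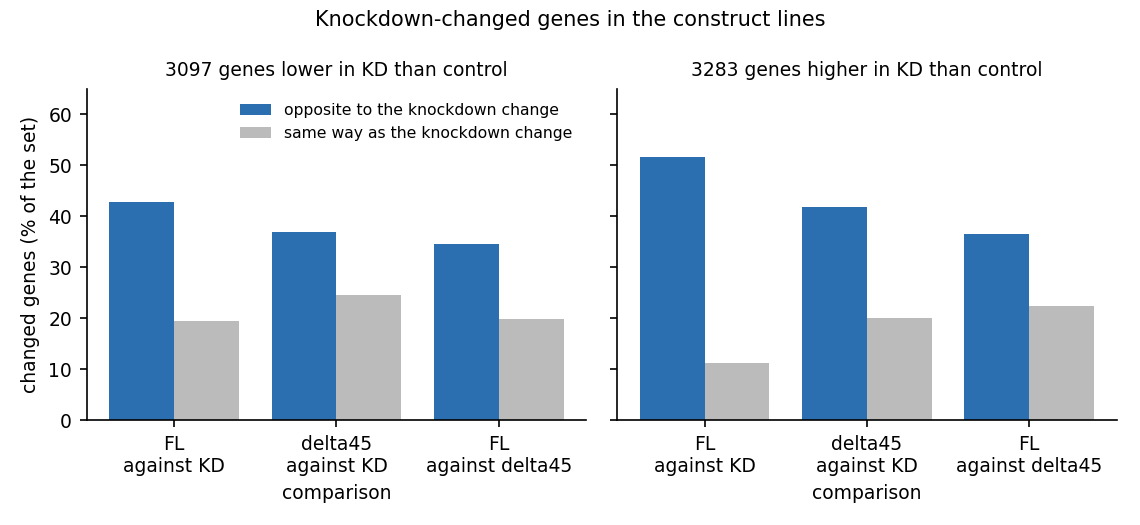
Percent (vertical axis) of the 3097 genes lower in KD and the 3283 genes higher in KD that changed in each construct comparison. Blue bars went opposite to the knockdown change and grey bars the same way; 42.8% of the genes lower in KD were higher in FL than in KD, and 36.9% higher in delta45 than in KD.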

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

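The tests of GC content, of a few strongly changed genes, of neighbouring genes, of depth, of multiple mapping and of Ldb1 amount, and the splits of the libraries, were written down only after their results were seen; the tests of whole segments and of whole chromosomes were written before.

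The changes of the 2 construct lines from the same KD libraries differed in 8 lists by the direct test of FL against delta45, camera at the preset correlation. That test does not separate the construct from the amount of Ldb1 mRNA or from other differences between the lines. With an estimated correlation 3 of the 8 were still called, with adjusted p = 0.00223 for DNA replication and mitosis, 0.00514 for ribosome biogenesis and MYC targets and 0.0124 for megakaryocyte markers. The other 5 were not, with adjusted p = 0.228 for globins, 0.471 for erythroid membrane and cytoskeleton, 0.471 for other erythroid maturation genes, 0.32 for autophagy and organelle clearance and 0.219 for hypoxia and glycolysis. The median log2 differences were 3.28 for globins, 0.97 for erythroid membrane and cytoskeleton, 0.92 for other erythroid maturation genes, 1.89 for megakaryocyte markers, -2.40 for DNA replication and mitosis, -1.46 for ribosome biogenesis and MYC targets, 0.75 for autophagy and organelle clearance, and 2.59 for hypoxia and glycolysis. Reads outside annotated genes, which no comparison used, made up 5.705% of the tallied reads in delta45 (SD 0.371, n = 3) and 4.003% in FL (SD 0.8305, n = 3), above the 3.08% of control.

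All 7 globin genes and 12 of 20 erythroid membrane genes were lower in delta45 than in FL, and 4 membrane genes were higher. Sequencing depth is argued against, since 19 of the 27 members were higher in FL before thinning to equal depth and 19 after. Loss of reads to multiple mapping was not settled. The share of such reads was 6.13 points higher in FL, but it covers whole libraries and does not measure the loss at these genes. The amount of Ldb1 mRNA and the form of LDB1 cannot be told apart, because FL also had more Ldb1 mRNA. Globin genes had a median of -2.64 in delta45 against control, where Ldb1 mRNA was not called different, so the altered form may matter, but the control cells are not a delta45 line and may differ in other ways.

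A set of 21 genes had 0 reads in KD and at least 5 CPM in control. Genes at that control level with 0 reads numbered 36 in FL and 34 in delta45. Depth is argued against for the 21, since the least abundant would have given 186 KD reads at its control level. The 5 CPM rule itself ensured a number of that order. Low LDB1 as the cause was not settled. Putting LDB1 back did not restore the genes, as 0 of the 21 reached 5 CPM in FL, but genes once silenced or lost need not return. Of the 19 that could be placed in gene order, 6 lay within 2 tested genes of another member, against a mean of 0.099 in random sets (permutation p = 0.0005, the smallest that 2000 sets can give). Of 63 neighbouring genes within 2 places, 4 (6.35%) were below 0.1 of their control level, more than the 1.78% of all placed genes. This argues against complete loss of segments of that reach around most of the set. It does not address partial loss of copies or loss of smaller segments, which that cut cannot detect. A difference between the cell lines that silences or removes small groups of neighbouring genes, apart from the amount of LDB1, may remain as a hypothesis.

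In delta45 against control, genes that the GRCm38 annotation places on chromosome 13 were shifted upward by a median of 0.64 log2 and those on chromosome 19 by -0.55, against 0.16 as the 95% limit of random sets. Shifts beyond such a limit were common, on 10 chromosomes here, 16 in KD against control and 12 in FL against control, and against control genes on chromosome 13 were also shifted by 0.22 in KD and 0.21 in FL, and those on chromosome 19 by 0.23 in KD and -0.10 in FL. Correction for GC content and transcript length left 0.51 and -0.56, and the quartiles moved by at least 0.62 and -0.54, which argues against these biases as the whole cause and against a few strongly changed genes, and each of 3 consecutive parts of the tested genes in order moved the same way, by at least 0.57 on chromosome 13 and -0.53 on chromosome 19. Against KD, the delta45 shift of chromosome 19 was -0.84, and -0.70 after that correction, but that of chromosome 13 was 0.34 and fell to 0.17, near the 0.14 limit there, so GC content or length may account for part of it. A change along whole chromosomes in the delta45 line may account for the rest, but copy number was not measured, the smaller shifts of other chromosomes and lines were not explained, and no comparison of groups separates such a line difference from the construct.

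With 3 libraries against 3, there are 10 splits and no share under 0.05 can be reached. The numbers of changed genes were 6380 for KD against control, where the highest of the other splits gave 4, and 7445, 7693, 6778, 7616 and 8271 for FL against KD, delta45 against KD, FL against delta45, FL against control and delta45 against control, where the highest of the others gave 0. In each comparison 1 of the 10 splits, the real one, gave as many genes. A split that mixes the groups puts their difference into the spread within groups, so few calls had to follow. The low counts of the other splits therefore add no support to the calls.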

How the results depend on the processing

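Thinning to equal depth was chosen after seeing the data. A test against a fold change of 1.5 called 2387, 3510, 3506, 3233, 3835 and 4596 genes for KD against control, FL against KD, delta45 against KD, FL against delta45, FL against control and delta45 against control. Under that test, genes lower in KD and higher in FL than KD, in delta45 than KD and in FL than delta45 numbered 336, 248 and 249, and genes higher in KD and lower in the same comparisons 441, 374 and 263. Library totals only gave 863, 650 and 1824 for genes lower in KD and higher in FL than KD, lower in KD and higher in FL than delta45, and higher in KD and lower in FL than delta45; the cause was not tested. Leaving out 1 library at a time gave 989 to 1749 genes lower in KD and higher in delta45 than KD. The lists called numbered 0, 1, 0, 3, 1 and 1 with an estimated correlation and 14, 15, 16, 16, 14 and 17 with fry, in the order above; fry asks another question, whether a list moves at all. For FL against control, 8 lists were called with no low-count filter, 3 at equal depth and 1 to 3 with a library left out, and for KD against control 4 to 7 with a library left out. The other alternatives kept each count they were run on within 1.5 times. DESeq2 and limma voom were run on the counts of changed and recovered genes, and fits on the compared groups alone on those of changed genes, so none of them on called lists. Of 114 gene results, 113 kept direction and call with DESeq2, RLE scaling, library totals only, the globin list left out (globin genes not included), a replicate block and each library left out, and Hba-a1 in delta45 against KD, not called at -0.13, ranged from -0.30 to 0.20 with a library left out, changing sign to 0.20 without KD replicate 3 and 0.02 without delta45 replicate 1. Many of these genes were named for a large fold or a small adjusted p in the same data. Their calls were therefore likely to hold, and they do not stand for called genes in general. Replicate numbers were not taken to pair the samples, since only 9 of 18 same-numbered pairs correlated over 0.1 after group means were removed. Their range was -0.196 to 0.269 and their median 0.1133, against -0.03275 for different numbers, the 9 pairs among KD, delta45 and FL were all above 0 (0.0315 to 0.248), and 8 of 12 libraries correlated best with their own number. A replicate block gave 6593, 7627, 7849, 6936, 7819 and 8408 changed genes and 7 called lists for delta45 against control, where myeloid markers and DNA replication and mitosis each had adjusted p = 0.0534. Counts of 0 limit the folds of genes without reads to bounds.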

Other observations

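The list tests and their alternatives were planned, except thinning to equal depth, and which lists to describe here was chosen after the results were seen.

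Genes of the unfolded protein and amino acid stress list were lower in FL than in control for 13 of 20 and higher for 2 (2 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.0673, 0.0365 without control replicate 3 and 0.034 with no low-count filter for unfolded protein and amino acid stress). Phgdh, an enzyme of serine synthesis, was 7.32-fold lower and Eif2ak1, the heme-regulated kinase, 2.9-fold higher. Cell cycle inhibitors and G1 regulators were 9 of 17 higher in FL than in delta45 and 4 lower (9 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.125, and 0.0457 with no low-count filter for cell cycle inhibitors and G1 regulators); Ccng2 was 6.05-fold higher and Rbl1 5.42-fold lower. Of 19 p53 target and apoptosis genes 11 were higher in FL than in control and 4 lower (11 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.115), Bcl2l11 8.17-fold higher. Of 18 iron handling genes 8 were higher and 5 lower (8 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.438), with Tfrc 7.39-fold higher and the ferrireductase gene Steap3 3.23-fold lower.

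Stem and progenitor genes in delta45 against control were 7 of 15 higher and 1 lower (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.119), with Gata2 2.55-fold higher and Spi1, the myeloid factor PU.1, 18.7-fold lower. All 6 tested mast and basophil markers were lower in FL than in control, at low levels (0 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0577, 0.0365 without control replicate 3, 0.034 with no low-count filter and 0.0485 at equal depth for mast and basophil markers). Their median was -3.63, or -2.44 with the member lacking reads at its bound. Of 22 hypoxia and glycolysis genes 7 were higher and 5 lower in KD than in control (7 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.378), and without KD replicate 1 the hypoxia and glycolysis list had 15 higher and camera adjusted p = 0.01. The median, mean and test differed in sign for megakaryocyte markers in KD against control (median 0.21, mean -0.28), and for cell cycle inhibitors there (median -0.15, mean 0.04). Signs also differed for the hypoxia list in FL against KD, the p53 list in delta45 against control, the other erythroid, LDB1 complex, stem and p53 lists in delta45 against KD, the stem list in both FL against delta45 and FL against control, and the megakaryocyte, ribosome and hypoxia lists in FL against control. With library totals only, medians changed sign for the iron, LDB1 complex, megakaryocyte, cell cycle inhibitor and hypoxia lists in FL against KD, the iron, LDB1 complex, FOG1 and NuRD, stem and myeloid lists in FL against delta45, the stem and cell cycle inhibitor lists in FL against control, and the p53 list in delta45 against control. The p53 list in KD against control changed sign with RLE scaling. The smaller count of a list moved by 1 gene with library totals only for megakaryocyte markers in FL against delta45 (1 lower), DNA replication and mitosis and unfolded protein genes in FL against control (0 and 1 higher), and ribosome biogenesis and hypoxia genes in delta45 against control (0 lower and 2 higher), and with RLE scaling for ribosome biogenesis genes in KD against control (1 lower) and autophagy genes in delta45 against control (0 higher).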
